A study of Mus musculus with 8 samples.

How the data were processed

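Gene expression was measured in femoral bone marrow of male C3H/HeSlc mice, 10 weeks old, on 8 two-colour Agilent whole-genome arrays. Each array compared 2 of 4 conditions: non-irradiated marrow given the methylcellulose vehicle (NM, called untreated marrow here), irradiated marrow given vehicle (IM), non-irradiated marrow given Zn-yeast (NZ) and irradiated marrow given Zn-yeast (IZ). The 8 arrays made 4 dye-swap pairs (IM/NM, IZ/NM, NZ/NM and IZ/IM), each pair holding 1 array with the labels Cy5 and Cy3 one way round and 1 array with them exchanged. Per the file headers, the IM/NM and IZ/NM pairs lay on slide 1 and the NZ/NM and IZ/IM pairs on slide 2.

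The deposited scanner files hold spot and local background brightness as intensity, without normalization, and a second set of intensity values that the authors' scanner software (Agilent Feature Extraction 9.5.3.1, per the file headers) had background-subtracted and dye-normalized. The same deposited files give the log10 of the processed Cy5 over the processed Cy3 signal, and the deposited series table holds these log10 ratios rounded, within 0.005 of the scanner value on every array. Each array had 45018 spots, of which 43379 were gene spots for 41174 probes. Median spot brightness was 158 to 176 in Cy5 and 110 to 117 in Cy3, over median local backgrounds of 44.0 to 56.0. Between 65.0% and 71.1% of the gene spots were well above background by the scanner's own test, 0 were saturated, and 92 to 151 spots per array were marked by the scanner as non-uniform or as population outliers and dropped. The number of arrays limits the precision. Ratios of dim genes are pulled towards 0 by the offset described next.

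The unnormalized intensities were corrected for background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0 and no scaling between arrays. Spots of a probe were averaged. A probe was kept when it was well above background on every array of at least 1 condition, which left 27572 probes. Probe names came from the accessions and symbols in the files, matched to a table of current mouse symbols (24375 probes by accession, 6301 by symbol and 2426 by an older symbol), and 8072 probes kept the name in the files. The probe with the highest mean brightness stood for each gene, which gave 18113 genes. Probes of the same gene can differ, and the mean of all probes was an alternative. Probe positions are those in the files, whose headers name genome build mm8.

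Both arrays of a pair were turned the same way and averaged, which cancels each gene's dye bias. A linear model in limma with 3 coefficients was fitted to the 4 averages, so that 1 residual degree of freedom per gene was left, moderated by empirical Bayes with 3.00 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The comparisons were irradiation without Zn-yeast (IM against NM), irradiation with Zn-yeast (IZ against NM), Zn-yeast without irradiation (NZ against NM), Zn-yeast after irradiation (IZ against IM), and the interaction, which is the difference between the last pair. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over 24 lists per comparison, and again with the correlation estimated from the 8 single arrays. The test with an estimated correlation was run on these single arrays with a dye effect, not on the pair averages. It thus differs from the first test in more than the correlation.

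The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named genes were the 10 largest rises and the 10 largest falls per comparison among called genes with a proper symbol whose direct arrays lay on the same side of 0, up to 4 members per list with the largest absolute change, and the check genes Cdkn1a, Mdm2, Ccng1, Bax, Mt1, Mt2 and Slc30a1. The text names part of these genes, and calls lost under an alternative were no ground for leaving a gene out. A list of 32 skeletal muscle genes was added after the data were seen. The procedure was tested on simulated arrays with the spread and dye bias of the real ones. For irradiation without Zn-yeast, 62.0% of 50 genes given a log2 change of 0.5 and 96.0% of those given 1 were called among 18113 genes. For Zn-yeast without irradiation the shares were 42.0% and 92.0%, and for Zn-yeast after irradiation 60.0% and 96.0%. For the interaction, 0 of 50 genes given 0.5 and 80.0% of those given 1 were called. A change of 0.25 was called for 0 of 50 genes in each of the comparisons before it. In these simulations 17913 of 18113 genes were left unchanged. The adjusted p cut-off was thus stricter than where many genes are called, so these shares do not carry over to the data.

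The labels do not give the number of mice behind an extract, and the dye-swap arrays of a pair compare the same labelled conditions. The p-values and errors of single genes therefore rest on the spread between arrays, not between mice. The camera p-values with the preset correlation compare the genes of a list with all other genes. They rest on the spread between genes and do not measure the spread between mice either. In the main fit the residual is how well the IM/NM, IZ/NM and IZ/IM averages add up. The difference between the arrays of a pair, which includes dye bias, does not enter. The NZ/NM average is fitted exactly, so errors for Zn-yeast without irradiation come from the other pairs and the moderation. Errors can therefore look small: Mt2 had 2.51 and 3.25 on the single NZ/NM arrays, with an SE of 0.04. The alternatives tried were no background correction, normexp with offset 10, median centring in place of loess, the processed signals, the series table, other filters on dim probes, the mean of all probes of a gene, an intensity trend with robust moderation, a fit to the 8 single arrays with a dye effect overall or per slide, a separate-channel fit, a 2-fold minimum, the estimated correlation, and leaving out each array in turn. When an array was left out, the other array of its pair was corrected with the dye bias of each gene from the other pairs and taken to vary like the pair averages. No column of per-sample values was left out for want of a mapping. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.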

Results

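Bone marrow was flushed from both femora 6 h after treatment, and total RNA of 4 conditions was compared on 8 arrays. Irradiated mice received 7.5 Gy of whole-body X-rays. Zn-yeast, a zinc-containing yeast powder, was injected intraperitoneally at 100 mg/kg (0.3 ml of an 8.5 mg/ml suspension) immediately after irradiation, and the vehicle was 0.5% methylcellulose. The design asks how marrow responds to irradiation, to Zn-yeast, and to Zn-yeast given after irradiation. Each of the 4 pairs of conditions was hybridized on 2 arrays with exchanged dyes. The log2 ratios of the pair's arrays correlated across genes with Pearson's r of 0.798 for IM/NM, 0.905 for IZ/NM, 0.672 for NZ/NM and 0.610 for IZ/IM. Genes are not independent replicates. Values below are log2 ratios ± SE from the fit to the 4 dye-swap averages. Apart from these arrays there were no replicates.

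After irradiation without Zn-yeast most target genes of p53, the transcription factor activated by DNA damage, were higher and most B-lineage genes lower, although neither list passed the test with an estimated correlation (adjusted p = 0.304 and adjusted p = 0.262). Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by 3.39 ± 0.08, a 10.4-fold change (adjusted p = 0.000497). Its probe lies on chromosome 17 at 28828096 to 28828155. Ccng1 (cyclin G1) rose by 3.31 ± 0.05, Phlda3, an inhibitor of Akt signalling, by 3.09 ± 0.04, and Mdm2, the ubiquitin ligase that degrades p53, by 1.25 ± 0.04. Vpreb1, part of the surrogate light chain of pre-B cells (chromosome 16, 16782029 to 16782088), fell by 4.61 ± 0.04, a 24.4-fold change (adjusted p = 0.000247).

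Of 43 measured p53 targets, 37 rose and 3 fell, with a median of 1.20 (adjusted p = 1.12e-10 by camera, adjusted p = 0.304 with an estimated correlation). Among regulators of apoptosis, the p53 targets Bbc3 (2.11 ± 0.04) and Bax (1.62 ± 0.05) rose, and Bmf, another pro-apoptotic member of the BCL2 family, fell by 2.10 ± 0.07, with its 3 probes between −2.10 and −0.20. The BCL2 and caspase list had 15 members up and 5 down of 28 (16 and 5 adjusted over the list alone), with a median of 0.16 that turned to −0.050 with median centring (adjusted p = 0.0266, adjusted p = 0.500 with an estimated correlation). That call was also lost with the processed signals. All 40 measured genes of S phase and DNA replication fell, by a median of −0.95 (adjusted p = 1.36e-16, adjusted p = 0.0671 with an estimated correlation). Examples are Ccne1 (cyclin E1, −1.58 ± 0.03), Uhrf1 (−1.28 ± 0.03), Pcna, the sliding clamp of DNA polymerase (−1.25 ± 0.03), and Mcm2, a subunit of the replicative helicase (−1.23 ± 0.03). Of 42 genes of G2 and mitosis, 35 fell and 3 rose (36 and 3 adjusted over the list alone), with a median of −0.31 (adjusted p = 1.87e-07, adjusted p = 0.105 with an estimated correlation). Espl1 (separase) fell by 0.77 ± 0.03, whereas Ube2c, which loads ubiquitin for the anaphase-promoting complex, rose by 1.11 ± 0.03. Of 32 genes of DNA repair and damage signalling, 29 fell and 1 rose (30 and 1 adjusted over the list alone), with a median of −0.53 (adjusted p = 1.34e-09, adjusted p = 0.105 with an estimated correlation). Ung, Xrcc6 and Parp1 fell by 1.13 ± 0.04, 1.13 ± 0.04 and 1.06 ± 0.03. Ribosome biogenesis and MYC target genes fell in 25 of 30 cases and rose in 1, with a median of −0.36 (adjusted p = 2.27e-07, adjusted p = 0.101 with an estimated correlation), Nop58 by 0.74 ± 0.03 and Nop56 by 0.66 ± 0.03.

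Among markers of marrow cell types, 32 of 36 B-lineage genes fell and 2 rose, with a median of −1.82 (adjusted p = 1.61e-11, adjusted p = 0.262 with an estimated correlation). Besides Vpreb1 they include Igll1, its partner in the surrogate light chain (−3.55 ± 0.18), Dntt, the terminal transferase of V(D)J recombination (−3.23 ± 0.05), Fcrla (−3.14 ± 0.13) and Rag1, the recombinase (−2.94 ± 0.13). Rag1 was well above background on 3 of the 4 spots of irradiated vehicle marrow, so the size of its fall is uncertain. Erythroid genes fell in 26 of 34 cases and rose in 4, with a median of −0.30 (adjusted p = 2.16e-05, adjusted p = 0.232 with an estimated correlation). Car1 (carbonic anhydrase 1) fell by 1.43 ± 0.03 and Add2 by 0.89 ± 0.03. The globin genes Hba-a1 (0.51 ± 0.03) and Hbb-bt (0.56 ± 0.04), chosen after their values were seen, rose, Hba-a1 with −0.53 and 1.52 on the single IM/NM arrays, and the call of Hba-a1 was lost with median centring. Neutrophil genes rose in 13 of 14 cases for the primary granule (median 0.53, adjusted p = 6.17e-06, adjusted p = 0.301 with an estimated correlation) and in 28 of 29 for the secondary granule and maturation (median 0.82, adjusted p = 6.56e-12, adjusted p = 0.232 with an estimated correlation). Chil3 rose by 1.43 ± 0.03 and Camp, the cathelicidin, by 1.21 ± 0.03. All 25 megakaryocyte and platelet genes rose, by a median of 0.67 (adjusted p = 1.44e-10, adjusted p = 0.232 with an estimated correlation), with Pf4 (platelet factor 4) at 1.54 ± 0.03. Of 33 monocyte and macrophage genes 29 rose, with a median of 0.75 (adjusted p = 6.39e-11, adjusted p = 0.262 with an estimated correlation). The scavenger receptor Marco rose by 3.25 ± 0.03 and Cd5l by 1.64 ± 0.03. Of 30 T and NK genes, 10 rose and 8 fell, and the list did not pass the test (adjusted p = 0.555), with a median of 0.03 and a mean of −0.0034. Its member Cd2, a T-cell adhesion molecule, fell by 0.92 ± 0.13, a call lost without array 1 of the IM/NM pair and a value of −1.77 with the processed signals. The stroma, endothelium and bone list rose in 29 of 33 cases and fell in 4, with a median of 0.63 (adjusted p = 1.87e-07, adjusted p = 0.301 with an estimated correlation). Spp1 (osteopontin) rose by 1.42 ± 0.03, and Acp5, the tartrate-resistant phosphatase of osteoclasts, fell by 1.35 ± 0.03.

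Interferon-stimulated genes rose in 40 of 41 cases, with a median of 0.84 (adjusted p = 1.1e-13, adjusted p = 0.301 with an estimated correlation). The interferon-inducible GTPases Iigp1 and Mx1 rose by 1.97 ± 0.04 and 1.58 ± 0.17, and Zbp1, a sensor of Z-form nucleic acid, by 1.42 ± 0.06. Inflammatory cytokines and NF-kB targets rose in 27 of 39 cases and fell in 4 (median 0.38, adjusted p = 4.65e-06, adjusted p = 0.389 with an estimated correlation), led by the chemokines Ccl2 (2.66 ± 0.08) and Cxcl9 (2.28 ± 0.06). The metallothionein genes, which encode zinc-binding proteins, rose by 0.76 ± 0.03 (Mt1) and 0.42 ± 0.03 (Mt2, a call lost with median centring). The zinc exporter gene Slc30a1 rose by 0.42 ± 0.04. Averaging all probes of a gene in place of the brightest gave −0.86 for Bmf, −2.05 for Igll1, −0.46 for Espl1 and 0.45 for Mt1, with the calls kept. With median centring the list medians were −0.55 for erythroid, −0.53 for G2 and mitosis, 0.26 and 0.51 for primary and secondary granule, 0.39 for megakaryocyte, 0.40 for stroma and −0.57 for ribosome biogenesis genes, all past the test, and Slc30a1 and Hbb-bt had 0.23 and 0.21. Apart from the lists of the mitosis, repair and BCL2 genes, the counts given here were the same adjusted over the list alone.

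Genes of skeletal muscle were also higher after irradiation. Of the 32 genes of the added list 31 rose, with a median of 1.55 (unadjusted camera p = 2.66e-11, p = 0.198 with an estimated correlation). That median was 2.28 on 1 IM/NM array and 0.73 on the other, 0.99 without array 1 of that pair, and 3.11 with the processed signals. Myh4, a member of the list, and Myh8, a myosin heavy chain outside it, rose by 4.24 ± 0.04 and 4.22 ± 0.09, and the connective tissue growth factor Ccn2 rose by 3.38 ± 0.03. In all, 11443 of 18113 genes were called, 5818 up and 5625 down, with a median absolute change of 0.30 among them, and 488 of these differed at least 2-fold (303 up and 185 down). Without array 1 of the IM/NM pair, 6286 genes were called. The direct arrays of this comparison all lay on slide 1.

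**Figure D1:**
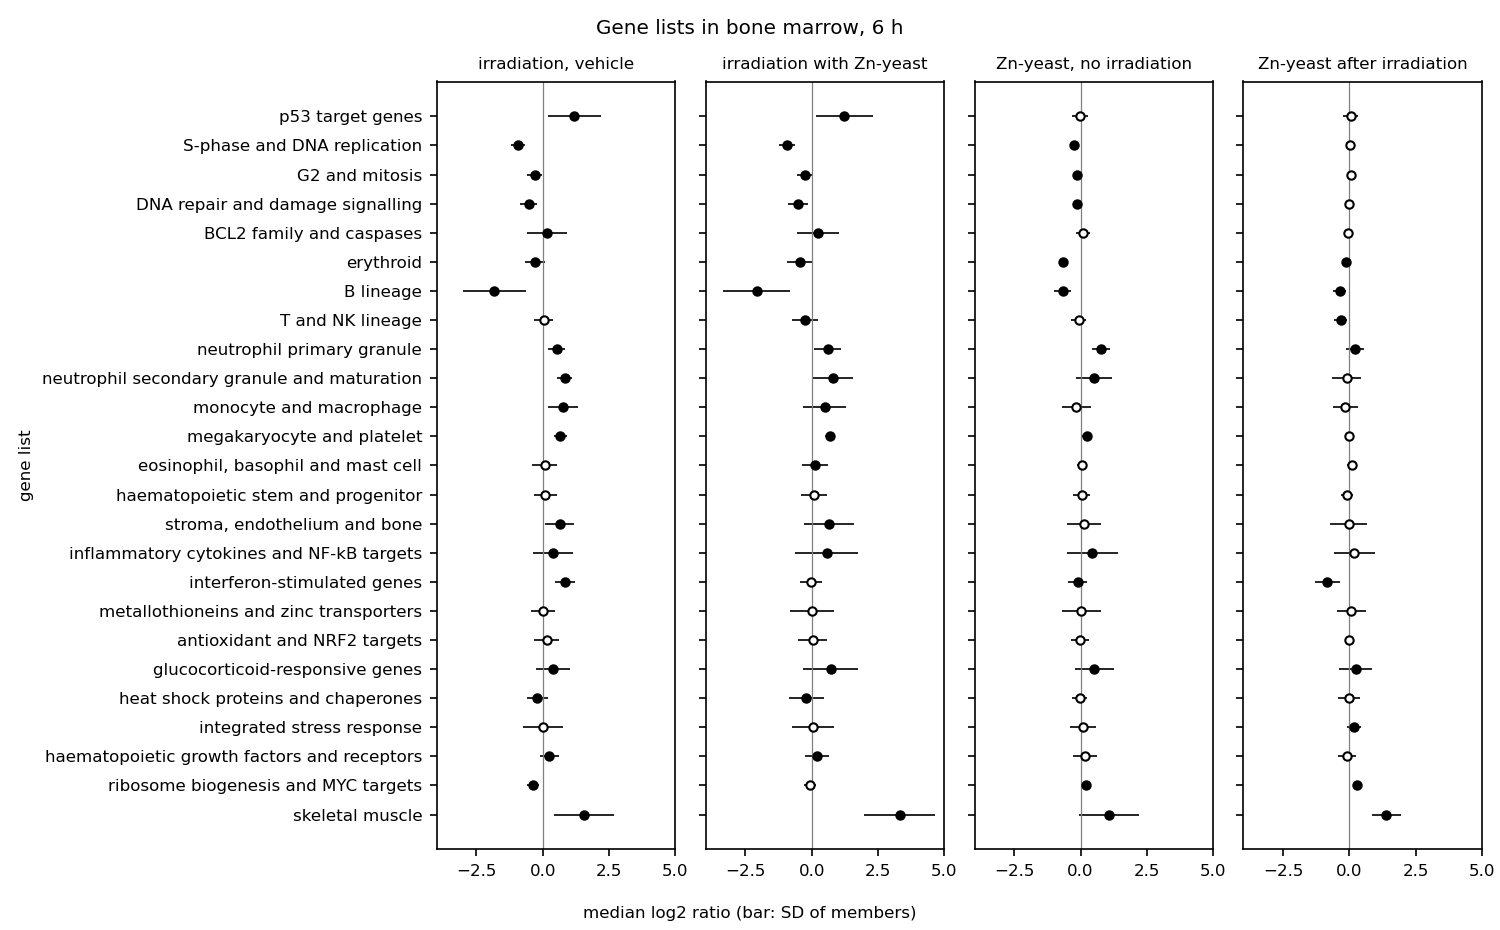
Median log2 ratio of each gene list (points) with the SD of its members (bars) in 4 comparisons on a common axis, filled where the camera test with the preset correlation passed (unadjusted for the muscle list) and open where it did not. S-phase genes lie at −0.95 after irradiation and interferon-stimulated genes at −0.84 for Zn-yeast after irradiation, and the skeletal muscle list lies above 0 in each panel.

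When Zn-yeast was given after irradiation, marrow compared with untreated marrow showed p53 target and cell-cycle changes of similar size. Of the 43 p53 targets 37 rose and 5 fell, with a median of 1.23 (adjusted p = 1.85e-09, adjusted p = 0.336 with an estimated correlation). Cdkn1a rose by 3.43 ± 0.08, Ccng1 by 3.35 ± 0.05 and Cgref1, a growth-regulatory EF-hand protein, by 3.65 ± 0.22. All 40 S-phase genes fell, by a median of −0.92 (adjusted p = 2.97e-15, adjusted p = 0.0790 with an estimated correlation), with Ccne1 at −1.64 ± 0.03 and Mcm2 at −1.35 ± 0.03. B-lineage genes fell in 35 of 36 cases, with a median of −2.08 (adjusted p = 8.39e-14, adjusted p = 0.252 with an estimated correlation), Vpreb1 by 5.57 ± 0.04 and Igll1 by 4.09 ± 0.18 (−2.39 as the mean of its probes). Igll1 was well above background on 3 of the 4 spots of irradiated Zn-yeast marrow, so the size of its fall is uncertain. These counts were the same adjusted over the list alone.

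Mt2 rose by 2.71 ± 0.03 and Mt1 by 2.06 ± 0.03 in this comparison, and Slc30a1 by 0.59 ± 0.04. Marco rose by 4.40 ± 0.03 and Cd14, a co-receptor for bacterial lipopolysaccharide, by 1.66 ± 0.05. Monocyte and macrophage genes rose in 29 of 33 cases and fell in 2 (median 0.49, or 0.30 with median centring, adjusted p = 4.47e-08, adjusted p = 0.328 with an estimated correlation). Of the interferon-stimulated genes, 13 rose, 17 fell and 11 were not called, and the list did not pass the test (median −0.041, adjusted p = 0.447). Mx1 rose by 1.33 ± 0.17, and Oasl2 fell by 1.09 ± 0.03. The acute-phase gene Saa3 rose by 3.58 ± 0.11, and the chemokines Ccl12 and Ccl2 by 3.90 ± 0.20 and 3.46 ± 0.08. Col1a1 (collagen type I) rose by 2.88 ± 0.03 (1.71 as the mean of its 3 probes) and Bglap (osteocalcin) by 2.83 ± 0.03. All 32 muscle genes rose, by a median of 3.31 (unadjusted camera p = 2.64e-15, p = 0.124 with an estimated correlation), led by Myl1 (5.39 ± 0.07, or 2.28 at its other probe) and Myh2 (5.32 ± 0.06). A total of 12057 genes were called, 6109 up and 5948 down, 726 of them at least 2-fold. Of the 24 lists 18 passed the test, against 0 with an estimated correlation, and the same counts held for irradiation without Zn-yeast.

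Zn-yeast without irradiation raised Mt2, Mt1 and the acute-phase gene Saa3 and lowered Il1b and Clec7a. Mt2 (chromosome 8, 97062600 to 97062659) rose by 2.88 ± 0.04, a 7.36-fold change (adjusted p = 0.00255), and Mt1 by 2.0 ± 0.04. Saa3 rose by 3.73 ± 0.14, a 13.3-fold change (adjusted p = 0.00367). Il1b, the cytokine interleukin-1 beta (chromosome 2, 129056052 to 129056111), fell by 2.11 ± 0.04, and Clec7a, the receptor dectin-1 for beta-glucans of yeast cell walls (chromosome 6, 129427414 to 129427473), fell by 1.69 ± 0.04. All 34 measured erythroid genes fell.

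The erythroid median was −0.64 (adjusted p = 1.29e-18, adjusted p = 0.0755 with an estimated correlation), with the erythroid transcription factor gene Klf1 at −0.82 ± 0.04 and Car2 at −0.82 ± 0.04. Hba-a1 had −0.86 ± 0.04, but its single NZ/NM arrays had opposite signs. B-lineage genes fell in 28 of 36 cases and rose in 1 (30 and 1 adjusted over the list alone), with a median of −0.67 (adjusted p = 1.55e-11, adjusted p = 0.295 with an estimated correlation). Fcer2a (CD23) fell by 1.09 ± 0.07 and Bank1 by 0.88 ± 0.04. Igll1 fell by 0.94 ± 0.22, a call lost in 9 alternatives, among them offset 10, the processed signals and, with a value of −0.77, leaving out array 2 of the NZ/NM pair. S-phase genes fell in 34 of 40 cases (36 adjusted over the list alone), with a median of −0.26 (adjusted p = 8.83e-12, adjusted p = 0.0755 with an estimated correlation), Ccne1 by 0.46 ± 0.04 and Dut by 0.44 ± 0.04. Genes of G2 and mitosis fell in 18 of 42 cases (21 adjusted over the list alone, median −0.14, adjusted p = 3.92e-06, adjusted p = 0.138 with an estimated correlation). Repair genes fell in 15 of 32 cases and rose in 1 (17 and 1 adjusted over the list alone, median −0.15, adjusted p = 4.58e-05, adjusted p = 0.209 with an estimated correlation). The helicase gene Wrn fell by 0.39 ± 0.06 and the checkpoint kinase gene Chek2 by 0.35 ± 0.04. Both calls were lost without array 1 of the IM/NM pair, and that of Wrn also with offset 10 or without array 2 of the IZ/IM pair.

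Neutrophil primary granule genes rose in 13 of 14 cases (14 adjusted over the list alone), with a median of 0.77 (adjusted p = 6.7e-10, adjusted p = 0.238 with an estimated correlation). Serpinb1a, an inhibitor of neutrophil proteases, rose by 1.19 ± 0.04 and Ms4a3 by 1.15 ± 0.06. Secondary granule and maturation genes rose in 18 of 29 cases and fell in 4 (21 and 4 adjusted over the list alone, median 0.50, adjusted p = 1.36e-05, adjusted p = 0.415 with an estimated correlation), with Il1r2, the decoy receptor for interleukin-1, at 2.28 ± 0.05 and Chil3 at 1.61 ± 0.04. Megakaryocyte genes rose in 20 of 25 cases (22 up and 1 down adjusted over the list alone, median 0.23, adjusted p = 1.28e-07, adjusted p = 0.295 with an estimated correlation), Pf4 by 1.09 ± 0.04. Monocyte and macrophage genes went both ways, 11 up and 16 down of 33 (12 and 17 adjusted over the list alone), and the list did not pass the test (adjusted p = 0.419), with a median of −0.16 and a mean of 0.05. Its members Marco and Cd14 rose by 2.22 ± 0.04 and 1.26 ± 0.06. Inflammatory genes rose in 21 of 39 cases and fell in 6 (24 and 7 adjusted over the list alone, median 0.45, or 0.28 without a filter on dim probes, adjusted p = 6.14e-05, adjusted p = 0.560 with an estimated correlation), Ccl2 by 2.30 ± 0.09. Ccl12 and, from the interferon list, Cxcl10 rose by 2.44 ± 0.25 and 1.04 ± 0.12, calls lost without array 1 of the IM/NM pair. Ribosome biogenesis and MYC target genes rose in 16 of 30 cases and fell in 1 (18 and 1 adjusted over the list alone, median 0.19, adjusted p = 1.07e-05, adjusted p = 0.104 with an estimated correlation), Myc itself by 0.50 ± 0.04.

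The p53 check genes were not called with Zn-yeast alone: Cdkn1a had 0.22 ± 0.10 (adjusted p = 0.170), Mdm2 0.05 ± 0.05, Ccng1 0.10 ± 0.07 and Bax −0.13 ± 0.06. Of 43 p53 targets 4 rose and 10 fell (adjusted p = 0.273, median −0.02), and Plk3 rose by 0.84 ± 0.05. Interferon-stimulated genes fell in 18 of 41 cases and rose in 5 (18 and 6 adjusted over the list alone, median −0.11, adjusted p = 0.0124, adjusted p = 0.792 with an estimated correlation), Oasl2 by 0.91 ± 0.04 and Isg15, a ubiquitin-like protein, by 0.85 ± 0.05. That list's call was lost without array 1 of the NZ/NM pair (median −0.09) and with the processed signals (−0.15), and its median was −0.18 without array 2 of that pair. The metallothionein and zinc transporter list did not pass the test (adjusted p = 0.193, median 0.03), with 9 of 25 members up and 3 down. Besides Mt1 and Mt2, the zinc importer gene Slc39a14 rose by 0.98 ± 0.10 (1.59 with the processed signals). Slc30a1 rose by 0.28 ± 0.05 (adjusted p = 0.0242), a call lost with offset 10, with median centring, and without array 1 of the IM/NM pair or array 2 of the IZ/IM pair.

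Among the largest changes in this comparison, Ccn2 rose by 3.38 ± 0.04, and Arg2 (arginase 2), Ifi27l2a, an interferon-induced gene, and Gbp11, a guanylate-binding protein, fell by 1.16 ± 0.04, 1.12 ± 0.04 and 1.10 ± 0.04. Muscle genes rose in 22 of 32 cases and fell in 2 (median 1.08, or 0.85 to 2.60 over the alternatives, unadjusted camera p = 9.74e-10, p = 0.252 with an estimated correlation), led by Myh2 (3.50 ± 0.07) and Myh1 (3.19 ± 0.12, or 1.15 as the mean of its 3 probes). Myh8, outside the list, rose by 3.35 ± 0.11. Altogether 5937 genes were called, 2995 up and 2942 down, 158 of them at least 2-fold (144 up and 14 down). Without array 1 of the IM/NM pair the count was 1657, without array 1 of the IZ/NM pair 3717 and without array 2 of the IZ/IM pair 2709. These arrays hold no non-irradiated Zn-yeast marrow, so leaving them out changed the errors and not the log2 ratios of this comparison. Both direct arrays lay on slide 2. Of the 24 lists 12 passed the test, against 0 with an estimated correlation.

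Zn-yeast after irradiation was compared directly with vehicle after irradiation, and interferon-stimulated genes were the list with the largest fall. Of 41 members 39 fell and 0 rose (40 and 0 adjusted over the list alone), with a median of −0.84 (adjusted p = 1.15e-24, adjusted p = 0.492 with an estimated correlation). Cxcl9, a chemokine induced by interferon-gamma (chromosome 5, 93398365 to 93398424), fell by 2.36 ± 0.06, a 5.14-fold change (adjusted p = 0.00149). Like Cxcl9, the GTPase gene Tgtp1 was not on that list, and it fell by 2.19 ± 0.03 (−0.86 at its other probe). Of the list, Iigp1 (chromosome 18, 60517868 to 60517927) fell by 2.28 ± 0.04, Oasl2 by 1.96 ± 0.03 and Rtp4 by 1.79 ± 0.03. Within slides, the list's median was −0.78 on slide 1, as IZ/NM less IM/NM, and −0.84 on slide 2, in the direct pair. The log2 ratios by these routes correlated across genes with Pearson's r of 0.887. The muscle list was higher in the same comparison, with 31 of 32 members up and a median of 1.39 (unadjusted camera p = 4.65e-19, p = 0.104 with an estimated correlation).

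**Figure D2:**
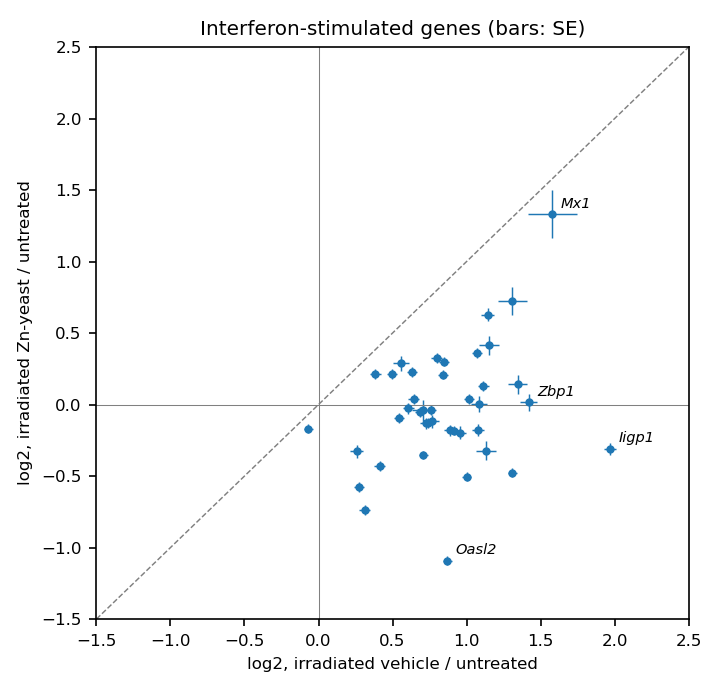
Log2 ratio of 41 interferon-stimulated genes against untreated marrow, in irradiated vehicle marrow on the x axis and in irradiated Zn-yeast marrow on the y axis, with SE bars and a dashed line where the values are equal. All 41 points lie below the line, with Iigp1 at 1.97 on the x axis and Mx1 at 1.33 on the y axis.

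As in non-irradiated marrow, Mt2 and Mt1 rose (2.29 ± 0.03 and 1.30 ± 0.03), and Il1b and Clec7a fell (1.98 ± 0.03 and 1.63 ± 0.03). Saa3 rose by 2.02 ± 0.11, Marco by 1.15 ± 0.03 and Cd14 by 0.88 ± 0.05. Col1a1 (chromosome 11, 94767851 to 94767910) rose by 2.68 ± 0.03, the cartilage collagen gene Col11a1 by 2.58 ± 0.04 and Bglap by 2.02 ± 0.03. The 3 probes of Col1a1 ranged from 0.25 to 2.68, with 1.65 as their mean. The stroma, endothelium and bone list, with 13 members up and 11 down of 33, did not pass the test (adjusted p = 0.623), and its median of −0.03 turned to 0.015 with median centring, where the list passed the test (adjusted p = 1.62e-06), while its mean was 0.23. It passed in 2 of 20 alternatives. Cdkn1a (0.05 ± 0.08, adjusted p = 0.694), Mdm2 (−0.06 ± 0.04), Ccng1 (0.04 ± 0.05) and Bax (−0.01 ± 0.05) were not called. The p53 list had a median of 0.04 and a mean of 0.07, and camera ranked it towards lower values without a call (adjusted p = 0.906). Its member Perp rose by 1.14 ± 0.14, the chemokine gene Ccl12 by 1.67 ± 0.20 and the zinc importer gene Slc39a14 by 0.61 ± 0.08. These calls were lost with offset 10 and without array 1 of the IM/NM pair or array 2 of the IZ/IM pair. Siglec1, a macrophage lectin, fell by 0.75 ± 0.05, but its other probe gave 0.0056 and the mean of both −0.37. Replication genes were not called as a list, with a median of 0.03 for S phase (adjusted p = 0.454).

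T and NK genes fell in 18 of 30 cases (19 adjusted over the list alone), with a median of −0.33, and the call held with an estimated correlation (adjusted p = 6.19e-09, adjusted p = 0.0341 with an estimated correlation). Ncr1, an activating receptor of NK cells, fell by 0.88 ± 0.03, the transcription factor gene Tbx21 by 0.68 ± 0.03 and Gzma (granzyme A) by 0.67 ± 0.03. Ribosome biogenesis and MYC target genes rose in 27 of 30 cases (30 adjusted over the list alone), with a median of 0.30, also with the estimated correlation (adjusted p = 4.56e-12, adjusted p = 0.0341 with an estimated correlation), Wdr43 by 0.50 ± 0.03, Nop58 by 0.47 ± 0.03 and Myc by 0.41 ± 0.03. B-lineage genes fell in 21 of 36 cases and rose in 1 (22 and 1 adjusted over the list alone, median −0.37, adjusted p = 1.39e-08, adjusted p = 0.60 with an estimated correlation), Vpreb1 by 0.96 ± 0.04. The B-cell transcription factor gene Ebf1 fell by 0.63 ± 0.09, a call lost with the mean of all probes and without array 1 of the IM/NM pair or array 2 of the IZ/IM pair. Lef1 of the same list fell by 0.65 ± 0.15, a call lost with offset 10, with the intensity trend, and without array 1 of the IZ/NM or IM/NM pair or array 2 of the IZ/IM pair. Erythroid genes fell in 12 of 34 cases (15 adjusted over the list alone, median −0.12, adjusted p = 0.000321, adjusted p = 0.492 with an estimated correlation). Neutrophil primary granule genes rose in 10 of 14 cases and fell in 1 (10 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.00823, adjusted p = 0.643 with an estimated correlation), a call lost in the separate-channel fit. Slc30a1 had 0.18 ± 0.04 (adjusted p = 0.0440), a call lost with offset 10, with median centring, with the mean of all probes, and without array 1 of the IZ/NM or IM/NM pair or array 2 of the IZ/IM pair.

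In this comparison 5365 genes were called, 2784 up and 2581 down, 161 of them at least 2-fold (107 up and 54 down). Of the 24 lists 8 passed the test, against 2 with an estimated correlation. The count was 1323 without array 1 of the IM/NM pair, 8267 without array 2 of that pair, 3109 without array 1 of the IZ/NM pair and 2306 without array 2 of the IZ/IM pair. The log2 ratios of IZ/IM and NZ/NM, which share no array and no condition, correlated across genes with Pearson's r of 0.566 and Spearman's rho of 0.454. Between single arrays of these pairs Pearson's r was 0.613 and 0.619 in the same dye orientation, and 0.298 and 0.327 in opposite orientations.

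**Figure D3:**
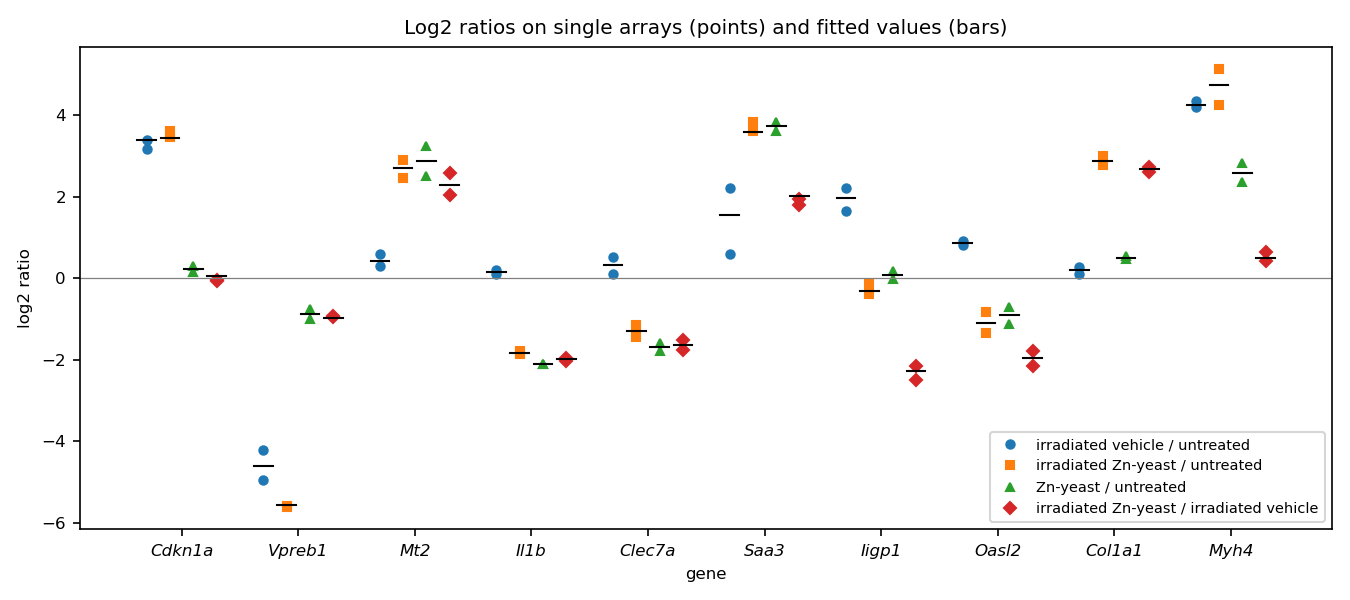
Log2 ratio of 10 genes on the single arrays (points, 2 per pair of conditions) with the fitted value (bars). Il1b, Clec7a and Mt2 lie on the same side of 0 in all 3 pairs with Zn-yeast in the numerator, and Vpreb1 lies at −4.61 and −5.57 in the pairs of irradiated over untreated marrow.

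The interaction asked whether the Zn-yeast effect differed between irradiated and non-irradiated marrow. A positive value means a higher signed log2 ratio of Zn-yeast over vehicle in irradiated marrow, which for genes that fell can be a smaller fall. Effects called higher or lower are meant in this signed sense. Median Zn-yeast effects without and after irradiation were −0.64 and −0.12 for erythroid genes. They were −0.26 and 0.03 for S-phase genes, and −0.67 and −0.37 for B-lineage genes. Cxcl9 had −2.60 ± 0.09 (adjusted p = 0.0155), Iigp1 −2.36 ± 0.07, Tgtp1 −1.87 ± 0.05 (−0.78 at its other probe) and Zbp1 −1.71 ± 0.09. Of 41 interferon-stimulated genes, 35 had a lower and 2 a higher Zn-yeast effect after irradiation (38 and 2 adjusted over the list alone), with a median of −0.69 (adjusted p = 1.48e-20, adjusted p = 0.213 with an estimated correlation). Col11a1 (2.28 ± 0.07), Col1a1 (2.18 ± 0.05) and Bglap (1.32 ± 0.05) had a higher effect after irradiation. Another probe of Col1a1 gave 0.24, and the mean of its probes was 1.34. The rises of Mt1 and Mt2 were smaller in irradiated marrow, by −0.70 ± 0.05 and −0.59 ± 0.06 (adjusted p = 0.0277 for each), with Mt1 at −0.42 as the mean of its probes.

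Erythroid genes were lower in non-irradiated Zn-yeast than in untreated marrow, where a difference of the untreated extract cannot be told apart from an effect of Zn-yeast. They had a higher Zn-yeast effect after irradiation in 29 of 34 cases (33 adjusted over the list alone), with a median of 0.50 (adjusted p = 2.74e-19, adjusted p = 0.0486 with an estimated correlation). Hba-a1 had 0.83 ± 0.05, with opposite signs on its single NZ/NM arrays. S-phase genes did so in 20 of 40 cases (34 adjusted over the list alone), with a median of 0.28 (adjusted p = 2.56e-14, adjusted p = 0.0486 with an estimated correlation), Pcna at 0.56 ± 0.05 and Tyms at 0.43 ± 0.05 (lost with the mean of all probes). T and NK genes had a lower effect in 10 of 30 cases (14 adjusted over the list alone), with a median of −0.17 (adjusted p = 1.24e-06, adjusted p = 0.0486 with an estimated correlation), and Gzmb (granzyme B) had −1.09 ± 0.07. Neutrophil secondary granule genes had a lower effect in 23 of 29 cases (27 adjusted over the list alone, median −0.51, adjusted p = 9.71e-17, adjusted p = 0.149 with an estimated correlation), S100a9 at −0.88 ± 0.05. Primary granule genes had a lower effect in 13 of 14 cases (13 adjusted over the list alone, median −0.48, adjusted p = 1.28e-10, adjusted p = 0.168 with an estimated correlation), Hp (haptoglobin) at −0.74 ± 0.05. Myh8 had −2.42 ± 0.14. On the muscle list, which lacks Myh8, Mylpf had 1.38 ± 0.05, and 11 of 32 genes had a higher and 6 a lower effect. The list's median of 0.47 did not pass camera for the interaction (unadjusted p = 0.0567). The list passed in 11 of 20 alternatives, and its median ran from −0.95 with the processed signals to 0.68 without array 1 of the IM/NM pair. Cdkn1a (−0.17 ± 0.13, adjusted p = 0.411), Mdm2 (−0.11 ± 0.06), Ccng1 (−0.06 ± 0.09), Bax (0.12 ± 0.07) and Slc30a1 (−0.10 ± 0.06) were not called.

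Of the 24 lists 15 passed the test for the interaction, against 3 with an estimated correlation. Genes of G2 and mitosis had a median of 0.18 (adjusted p = 2.41e-08, adjusted p = 0.0754 with an estimated correlation), DNA repair genes 0.15 (adjusted p = 2.6e-05, adjusted p = 0.149 with an estimated correlation) and B-lineage genes 0.32 (adjusted p = 0.000307, adjusted p = 0.516 with an estimated correlation). The B-lineage median was 0.14 without array 2 of the NZ/NM pair, where the call was lost, and 0.18 without array 1 of the IM/NM or IZ/IM pair. Megakaryocyte genes had −0.27 (adjusted p = 1.59e-09, adjusted p = 0.213 with an estimated correlation) and inflammatory genes −0.16, or −0.27 with the processed signals (adjusted p = 0.000366, adjusted p = 0.516 with an estimated correlation). For the interaction 1853 genes were called, 854 higher and 999 lower, 77 of them at least 2-fold. Limma called 0 genes with offset 10 (5210 at an unadjusted p under 0.05) and 0 without array 2 of the IZ/IM pair (4247 at an unadjusted p under 0.05), against 4938 in the fit to 8 single arrays, so every call of a named gene was lost in both of these settings. The count was 11 without array 1 and 6025 without array 2 of the IM/NM pair, 38 without array 1 and 2873 without array 2 of the IZ/NM pair, and 2902 without array 1 of the IZ/IM pair.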

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

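The lists and genes named first were picked because the Zn-yeast effect differed between irradiated and non-irradiated marrow in the test of the interaction, and the patterns after them from the values of all comparisons. All tests of explanations in this part were chosen after the patterns had been seen, and the bounds for the muscle genes were set and tightened after the values they were applied to had been seen. A total of 1853 genes passed the test of the interaction. Of the 15 gene lists past it with the preset correlation, only the erythroid, S-phase and T and NK lists passed with an estimated correlation. The median interaction was −0.69 for interferon-stimulated genes, −0.51 and −0.48 for neutrophil secondary and primary granule genes, and −0.27 for megakaryocyte and platelet genes. It was −0.22 for glucocorticoid-responsive genes, −0.17 for T and NK genes, −0.16 for inflammatory genes, −0.13 for growth factors and their receptors, and −0.10 for stem and progenitor genes. It was 0.50 for erythroid, 0.32 for B-lineage (0.14 and no longer past the test without array 2 of the NZ/NM pair), 0.28 for S-phase, 0.18 for G2 and mitosis, 0.15 for DNA repair and 0.12 for ribosome biogenesis genes.

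Among single genes with a lower Zn-yeast effect after irradiation, Cxcl9 had −2.60, Iigp1 −2.36, Tgtp1 −1.87 (−0.78 at its other probe), Zbp1 −1.71, Cxcl10 −1.63 and Oas2 −1.30 (−0.85 as the mean of its probes), all of them induced by interferon. The chemokine Ccl2 had −1.49, Saa3 −1.71 (−2.62 with the processed signals), Socs3 −0.98, the growth factor Csf1 −0.61, Ccn2 −2.10, and the scavenger receptor Marco −1.07. Pf4 had −1.72, and genes of bone resorption and matrix, Ctsk (cathepsin K) and Spp1, had −1.77 and −1.21. The ion exchanger gene Slc9b2 had −1.93 (−3.43 with the processed signals), the myosins Myh8 and Myh4 −2.42 and −2.09 (Myh4 lost its call in the separate-channel fit), and Errfi1 and Il1r2, which glucocorticoids raise, −1.45 and −0.86. Mt1 and Mt2 had −0.70 (−0.42 as the mean of its probes) and −0.59, the neutrophil genes Plac8, Hp, S100a9 and Stfa3 −0.76, −0.74, −0.88 and −0.91, and the granzymes Gzmb and Gzma −1.09 and −0.56. With a higher effect after irradiation, Col11a1 had 2.28, Col1a1 2.18 (1.34 as the mean of its probes), Bglap and Bglap3 (osteocalcins) 1.32 and 1.28, and the adipocyte protease Cfd 1.11. Mylpf had 1.38, Smtnl2 1.40 (2.24 with the processed signals) and Ppp1r3c 1.34 (a call lost with the processed signals). Trim63, a ubiquitin ligase of muscle, had 1.48, but its spots were well above background on 1 of the 6 untreated measurements and its sign changed with the processed signals. Hba-a1 and Hbb-bt had 0.83 and 0.76, Pcna, Pola1 and Mki67 0.56, 0.52 and 0.46, Tyms 0.43, and Pou2af1, Bank1 and Dntt of the B lineage 0.90, 0.57 and 0.96. The calls of Tyms and Dntt were lost with the mean of all probes.

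Interferon-stimulated genes were lower in irradiated Zn-yeast marrow than in irradiated vehicle marrow, with a median of −0.84, and the list did not pass the test with an estimated correlation (adjusted p = 0.492). Dilution of the marrow RNA by muscle and bone RNA would have lowered the markers of all marrow cell types about as far, but the median of 219 markers of 8 cell types was −0.10 with an SD of 0.37. Under 6 other settings of background correction and normalization the list's median was at most −0.77, which argues against these steps. These are not 6 separate checks. Among them, the series table holds the ratios of the processed signals rounded, and the separate-channel fit keeps the main background correction and loess. Against untreated marrow, the list's median was −0.041 in irradiated Zn-yeast marrow and −0.11 in Zn-yeast marrow, so an irradiated vehicle extract that stood apart for a reason other than the treatment cannot be told apart from an effect of Zn-yeast, since each condition may rest on a single extract. That Zn-yeast holds back the interferon response to irradiation stays open as a hypothesis, which further extracts from other mice of both irradiated conditions would test.

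Genes of skeletal muscle were higher than in untreated marrow in all 3 other conditions, and 24 of the 32 were above background on all 6 untreated measurements, with a median above 0 on 8 of 8 arrays, which argues against a slide or dye effect. A candidate explanation is muscle tissue of 1 fixed composition, carried over from around the femur in different amounts, which predicts 1 ratio of the excess over untreated marrow between any pair of conditions. Between irradiated Zn-yeast and irradiated vehicle marrow, 81.2% of the 32 genes lay within 2-fold of the median ratio of 4.16 (50% and 75.0% in single dye orientations), from 1.43 for Myh4 to 17.5 for Cox6a2, so this part cannot be told apart with 2 arrays per pair. Between non-irradiated Zn-yeast and irradiated vehicle marrow only 56.2% did (37.5% and 50%), with 0.280 for Myh4 and 3.25 for Myh1, and Car3 fell by 0.27 with Zn-yeast alone. Between the Zn-yeast conditions 65.6% did. These ratios were taken with offset 50 only and have no errors. The 3 probes of Myh1 ran from 0.13 to 3.19 with Zn-yeast alone. Over the alternatives the list's median ran from 0.99 to 3.11 with irradiation and from 0.85 to 2.60 with Zn-yeast alone. The same composition in both is therefore not excluded. Mean log2 brightness of Tnni2 was 10.8 in untreated, 12.0 in Zn-yeast, 13.5 in irradiated vehicle and 14.9 in irradiated Zn-yeast marrow. Carry-over of muscle of 1 composition stays open, as do carry-over of varying composition and an effect of the treatments on muscle genes, both untested.

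Irradiation and Zn-yeast moved more genes the same way than opposite ways against untreated marrow, with Pearson's r of 0.491 across 18113 genes and 3621 shared calls in the same and 920 in opposite directions. Simulated arrays without any effect gave r between −0.06 and 0.06 in 100 draws. Their noise was independent between arrays, and these estimates share no array, so a value near 0 was fixed in advance. The simulation held no difference of the shared untreated extract and cannot weigh it. The ribosome biogenesis genes (medians of −0.36 with irradiation and 0.19 with Zn-yeast) and Hba-a1 (0.51 and −0.86, with single arrays of each pair on both sides of 0) went opposite ways. The medians of the interferon-stimulated genes (0.84 and −0.11) also had opposite signs. With Zn-yeast, however, only 18 of 41 were called lower, 5 were called higher and 18 were not called. In the IZ/IM pair, which holds no untreated marrow, erythroid genes had a median of −0.12, against −0.64 in the NZ/NM pair. The effect of Zn-yeast after irradiation correlated with that of irradiation with r of 0.0711 (1646 shared calls in the same and 2245 in opposite directions). Irradiated vehicle marrow enters both with opposite signs, and the estimates share arrays. Array noise alone, the only variance in the simulated arrays, gave a mean r of −0.501. Its mean covariance was only −0.0016, against 0.0068 observed, so these r values cannot be set side by side. An untreated extract with more erythroid and fewer granulocyte transcripts than the others cannot be told apart, for the genes that moved the same way, from treatment effects that do not add up, since untreated marrow enters every other pair. A systemic stress response to either treatment would be 1 such effect, a hypothesis that was not tested.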

How the results depend on the processing

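The skeletal muscle list, and counts and correlations without it, were added after seeing the data. No paired analysis was possible because the labels number no animals. Leaving out the muscle list kept all counts within 1.5 times. It removes only 32 of 18113 genes, after normalization, so the counts could hardly have moved further. This outcome does not weigh carry-over of muscle. Among the named genes and lists, 4 values that passed the test in at least 1 of the settings compared changed sign: Trim63 in the interaction (−0.70 with the processed signals and −0.70 with the series table), the BCL2 and caspase list after irradiation without Zn-yeast (−0.050 with median centring), and the stroma, endothelium and bone list for Zn-yeast after irradiation (0.015 with median centring). Values that passed in neither setting also changed sign, such as the muscle list in the interaction (−0.95 with the processed signals) and the antioxidant list after irradiation without Zn-yeast (−0.11 with median centring). The cause was not tested.

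The number of called genes depended on the processing. For Zn-yeast after irradiation it was 10625 without background correction, 2885 with offset 10, 2724 with median centring, 8161 with the processed signals, 8152 with the series table and 8926 in the separate-channel fit. For Zn-yeast without irradiation it was 10947 without background correction, 3554 with offset 10, 3000 with median centring and 9602 in the separate-channel fit. For the interaction it was 8933 without background correction, 0 by limma with offset 10 (5210 at an unadjusted p under 0.05), 950 with median centring, 5362 with the processed signals, 5343 with the series table, 5145 with an intensity trend and robust moderation, 6699 in the separate-channel fit, 4938 in the fit to 8 arrays and 4393 with a dye effect per slide. Asking for a 2-fold change as well left 488 genes for irradiation without Zn-yeast, 726 for irradiation with it, 158 for Zn-yeast without irradiation, 161 after irradiation and 77 for the interaction, by construction fewer. With an estimated inter-gene correlation, the lists past the test went from 18 to 0 for irradiation without Zn-yeast, 18 to 0 for irradiation with it, 12 to 0 for Zn-yeast without irradiation, 8 to 2 after irradiation and 15 to 3 for the interaction. That test also used the single arrays in place of the pair averages, so the lost calls cannot be put down to the correlation alone. For T and NK genes the estimate was 0.0047, below the preset 0.01. Their camera call for irradiation with Zn-yeast was nevertheless lost (adjusted p = 0.0161 against adjusted p = 0.242). For the other changes the cause was not tested.

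Leaving out each array in turn gave 6286 to 13563 genes for irradiation without Zn-yeast, 8202 to 13420 with it, 1657 to 8605 for Zn-yeast without irradiation, 1323 to 8267 after irradiation and 0 to 6025 for the interaction. The lists past the test ranged over 17 to 19, 16 to 18, 11 to 14, 8 to 10 and 14 to 16, and the correlation of the Zn-yeast effects over 0.495 to 0.597. For Zn-yeast without irradiation, leaving out an array of a pair other than NZ/NM changes the errors only, since the NZ/NM average is fitted exactly. Spot signal over background limits dim genes: Baiap2l1, among the largest interaction values by the naming rule, was at background in non-irradiated Zn-yeast marrow and is given no fold. Of 321 values of single genes, 55 lost their call without array 2 of the IZ/IM pair, 54 with offset 10, 51 without array 1 of the IM/NM pair, 30 without array 1 of the IZ/NM pair and at most 5 in each other alternative. Of 125 list values, 7 lost their call with the processed signals and 5 with median centring, where 7 gained one.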

Other observations

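Further lists describe responses outside the main themes. Glucocorticoid-responsive genes rose in 13 of 17 cases and fell in 2 (13 and 2 adjusted over the list alone) after irradiation without Zn-yeast, with a median of 0.40, or 0.13 with median centring (adjusted p = 0.00197, adjusted p = 0.304 with an estimated correlation). They rose in 13 and fell in 2 (13 and 3 adjusted over the list alone) with Zn-yeast alone (median 0.52, adjusted p = 6.06e-05, adjusted p = 0.295 with an estimated correlation), and rose in 11 and fell in 3 (11 and 3 adjusted over the list alone) with Zn-yeast after irradiation (median 0.24, adjusted p = 0.0134, adjusted p = 0.643 with an estimated correlation). Pdk4, which restrains glucose oxidation, rose by 1.22 ± 0.13 (2.12 with the processed signals), 1.42 ± 0.16 and 1.95 ± 0.13 in these comparisons, and by 3.17 ± 0.13 in irradiated Zn-yeast against untreated marrow. Errfi1 rose by 1.93 ± 0.05 after irradiation and by 1.69 ± 0.06 with Zn-yeast alone, and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.88 ± 0.04 with Zn-yeast after irradiation. The muscle list was also higher in each of these comparisons, with medians of 1.55, 1.08 and 1.39.

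The integrated stress response list rose in 14 of 22 cases and fell in 3 (14 and 4 adjusted over the list alone) with Zn-yeast after irradiation (median 0.18, adjusted p = 0.00823, adjusted p = 0.492 with an estimated correlation), Vldlr by 0.76 ± 0.05 and Chac1, a glutathione-degrading enzyme, by 0.61 ± 0.05. It did not pass the test with Zn-yeast alone (adjusted p = 0.0762), where it passed in 8 of 20 alternatives and Cebpb rose by 1.17 ± 0.04. Nor did it pass after irradiation (adjusted p = 0.842), where the list had a median of 0.0069, a mean of 0.07 and a camera ranking towards lower values. Sesn2 rose by 1.86 ± 0.04 there and Asns, the asparagine synthetase, fell by 1.15 ± 0.03. Haematopoietic growth factors and receptors rose in 13 of 21 cases and fell in 2 (14 and 2 adjusted over the list alone) after irradiation, with a median of 0.25 (adjusted p = 0.00202, adjusted p = 0.323 with an estimated correlation), a call lost with median centring. Csf1 rose by 1.18 ± 0.05 there. With Zn-yeast alone, Csf2rb, the shared beta chain of cytokine receptors, rose by 1.13 ± 0.04 (0.70 as the mean of its probes) and Csf3r, the receptor for G-CSF, fell by 0.72 ± 0.04. Csf3r fell by 0.83 ± 0.03 with Zn-yeast after irradiation as well. Heat shock proteins and chaperones fell in 12 of 19 cases and rose in 5 (12 and 6 adjusted over the list alone) after irradiation (median −0.20, or −0.46 with median centring, adjusted p = 0.0423, adjusted p = 0.500 with an estimated correlation), Hsph1 by 0.73 ± 0.03, and that call was lost in 7 alternatives, among them the processed signals, no background correction, and leaving out array 2 of the IM/NM or IZ/NM pair (medians −0.18 and −0.21 for the last pair). After irradiation without Zn-yeast the antioxidant list (adjusted p = 0.0764, median 0.14, or −0.11 with median centring), stem and progenitor genes (adjusted p = 0.0764, median 0.10), eosinophil, basophil and mast cell genes (adjusted p = 0.448, median 0.07) and the zinc list (adjusted p = 0.840, median −0.00031) did not pass the test. Single members were called nevertheless, with the haem oxygenase Hmox1 at 1.61 ± 0.03, Ly6a (Sca-1) at 1.51 ± 0.09 and Il1rl1, the receptor of interleukin-33, at −1.29 ± 0.03. The 3 probes of Il1rl1 ranged from −1.29 to −0.069, with −0.67 as their mean. For the interaction, glucocorticoid-responsive genes (adjusted p = 0.00044, adjusted p = 0.258 with an estimated correlation), growth factors and receptors (median −0.13, or −0.19 without array 2 of the NZ/NM pair, adjusted p = 0.00044, adjusted p = 0.342 with an estimated correlation), stem and progenitor genes (adjusted p = 0.0094, adjusted p = 0.516 with an estimated correlation) and ribosome biogenesis genes (adjusted p = 0.00115, adjusted p = 0.149 with an estimated correlation) passed the test with the preset correlation.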
